A study of Mus musculus with 4 samples.

How the data were processed

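RNA-seq libraries from thigh skeletal muscle of male C57BL/6J mice were compared between 28 months (3 libraries) and 18 months (1 library). Per the labels, reads were converted with bcl2fastq 1.8.3 and aligned with TopHat2 2.0.4 to GRCm38. The deposited tables hold raw counts per exonic bin, 1 table per library, with no normalization. The counter, the annotation release and the strand setting were not given in the sources used here. The form of the bin names and of the 5 special entries is that of the DEXSeq counting script, in which a fragment that spans several bins counts in each, so that a sum over a gene's bins counts a fragment more than once. The 5 special entries, which name no gene, equalled 3.43, 4.56 and 3.36% of the entries' total in 28-month replicates 1, 2 and 3 and 5.20% at 18 months, and were left out.

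Bins numbered 374286, in 40137 gene units, of which 949 join several genes. Totals were 76163175, 75992582 and 67279205 counts at 28 months and 65780464 at 18 months, and TMM factors were 0.877, 1.28, 0.897 and 0.990 in the same order. The most abundant 20 genes took 35.3, 25.7, 36.0 and 33.5% of counts. No pair of libraries was a duplicate, with chi-square over degrees of freedom of 79.4 to 610.

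Bins were summed per gene, and units with a mean count of at least 10 over the 4 libraries were tested with the edgeR quasi-likelihood test after TMM scaling. The fit had 2 residual degrees of freedom, all from the 28-month libraries, and 3.17 prior degrees of freedom. Gene and exon usage fits that left out a 28-month library took their residual spread from the remaining pair alone. The common biological coefficient of variation was 0.378. Exon usage was tested with edgeR diffSpliceDGE, with Simes p-values per gene, on bins with a mean count of at least 10 in genes with several such bins. Bins that join several genes were left out of it. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Lists were tested for expression with limma camera, two-sided, with a preset correlation of 0.01 (22 lists), and for exon usage with a two-sided Fisher's exact test against all other tested genes (4 lists). Exon usage distance was the mean absolute difference in bin share over genes with a mean of at least 100 counts, after thinning each library to 59849699 counts.

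Gene positions came from GENCODE release M21 on GRCm38, and no genome sequence was at hand. Bin positions were used only for genes whose number of bins equalled that of the flattened M21 annotation, 16779 of 24942 genes with several bins (67.3%). An equal number of bins does not prove that the placement is right. Processed pseudogenes were matched to their parent genes by BLAST over at least 100 bases (7148 matched). GC content and length of the longest transcript were known for 95.1% of genes.

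The tests, lists and naming rule were fixed before the data were examined. Genes named for expression were to be those past the threshold with the largest changes. As fewer than 6 passed in a direction, the 6 with the smallest p in each direction were named as not passing, at a mean of at least 1 CPM and with predicted genes left out. Exon usage genes named were the 12 with the smallest gene p, with 1 bin each. Up to 4 members of each list could be named, and 18 genes were fixed by name. Not every gene that the rule names is given.

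Alternatives fixed in advance were DESeq2 size factors, other count filters, the DESeq2 Wald test, leaving out each 28-month library, library size without mitochondrial and the 20 most abundant genes, limma voom with diffSplice, the gene F-test, DESeq2 on bins, leaving out first and last bins, an estimated correlation, fry, and other forms of the distance. Added after the data were seen were the removal of GC and length trends, limma quality weights, and restriction of exon usage to placed genes, to placed genes without intron-side and end bins, and to genes with no processed pseudogene. No fit could use more than 1 library at 18 months.

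The pipeline was tested on simulated data with 200 changed genes, drawn from those with a mean count of at least 100 (per bin for exon usage). With the spread of all 4 libraries, the gene test recovered 8, 44, 92 and 100% of changes of log2 1, 2, 3 and 4. With the spread left after dropping 28-month replicate 2, but all 4 libraries still drawn, it recovered 60, 86, 100 and 100%. The fit with that replicate left out was not itself simulated. For exon usage with independent bins and the spread of all 4 libraries, it recovered 0% at log2 1 and 5% at log2 2. With a low spread and no gene effect it recovered 46 and 97%, and with a shared gene effect 0 and 0%.

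Programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, mgcv 1.9.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and BLAST 2.17.0.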

Results

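RNA was sequenced from thigh skeletal muscle of male C57BL/6J mice, an inbred laboratory strain, at 28 months (3 libraries) and at 18 months (1 library). The sequencing was meant to check an exon array analysis of alternative splicing in the same samples, and those arrays were not part of the data used here. The deposited tables held raw counts for 374286 exonic bins, pieces of exon between annotated boundaries. The bins summed to 76163175, 75992582 and 67279205 counts in 28-month replicates 1, 2 and 3 and to 65780464 counts in the 18-month library. Exact confidence intervals and limits below cover counting error only. The bootstrap interval given later resampled pairs of bins within the same 4 libraries and measured no spread between samples. The p-values of the gene and bin tests measured the spread between these samples, which the labels do not otherwise tie to separate animals. The lone 18-month library was assumed to vary like the 28-month libraries. Fisher's exact tests took genes or bins as units, over calls that rest on the same 4 libraries, so their p-values measured no spread between samples. Camera p-values compared listed genes with all others and depended on the correlation used.

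Muscle transcripts filled all 4 libraries and keratin transcripts were close to absent. This comparison asked which tissue the libraries came from, because the labels give thigh skeletal muscle while their extraction text describes epidermal cells of skin. The genes of fast glycolytic fibres, which make the contractile and energy proteins of fast muscle, summed to 262577, 131734 and 266676 CPM, the normalised read count used throughout, in 28-month replicates 1, 2 and 3 and to 161953 CPM at 18 months. Genes of epidermal keratinocytes summed to 22.1, 22.9 and 28.4 CPM at 28 months and 25.4 CPM at 18 months. Krt5, a keratin of the basal epidermis chosen here after its values were seen, had 0 counts in all 4 libraries, which allows up to 3 counts per library. Krt10, a keratin of the upper epidermis, had 74, 109 and 56 counts at 28 months and 55 at 18 months.

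Under a preset correlation, macrophage markers were higher as a group in 28-month muscle and Schwann cell markers were lower. Neither list was called with a correlation estimated from the data (adjusted p 0.993 by limma camera), and the macrophage call was also lost without 28-month replicate 2 (0.0766). Connective tissue, collagen and fibre type genes were not separated between the ages by the list test on all 4 libraries. No single gene passed the edgeR test on all 4 libraries (753 at an unadjusted p under 0.05, 34 by DESeq2 and 1 by limma), and 1806 passed without 28-month replicate 2, 2 without replicate 1 and 1 without replicate 3. This comparison asked which transcripts differed in amount between 28 and 18 months.

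Across 15376 genes or joined gene units, the edgeR quasi-likelihood test called 0 at a Benjamini-Hochberg adjusted p under 0.05, with a smallest adjusted p of 0.859. At an unadjusted p under 0.05 there were 753, of which 390 were higher and 363 lower at 28 months. The DESeq2 Wald test called 34 and limma voom with quality weights called 1. Leaving out 28-month replicate 1 gave 2 genes, leaving out replicate 2 gave 1806 (1137 higher and 669 lower at 28 months), and leaving out replicate 3 gave 1. The 18-month value lay outside the range of the 28-month values for 7968 genes (51.8%), where chance gives 50%. Across 12529 genes, which are not independent replicates, log2 CPM correlated at r = 0.981 between 28-month replicates 1 and 3, and at 0.930 between replicate 2 and either of them. The fit without replicate 2 took its residual spread from replicates 1 and 3 alone, the closest pair. The 18-month library correlated at 0.957, 0.950 and 0.951 with replicates 1, 2 and 3, higher than replicate 2 did with its own group.

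The genes with the smallest p in each direction did not pass the test, and those given here each had an edgeR adjusted p of 0.859. Higher at 28 months in estimate was Por, the reductase that passes electrons to cytochrome P450 enzymes (ENSMUSG00000005514, GRCm38 chromosome 5, 135670033 to 135735326), at 67.3 ± 1.65 CPM (SD, n = 3) against 20.1 CPM at 18 months, a log2 difference of 1.74 ± 0.28 (SE). Rpl22l1, a relative of a ribosomal protein (ENSMUSG00000039221, chromosome 3, 28805436 to 28807424), stood at 27.6 ± 3.60 CPM against 7.02 CPM, a log2 difference of 1.97 ± 0.31. Ndufa3, a subunit of respiratory complex I, had a log2 difference of 2.03 ± 0.35. Pet100, which helps build cytochrome oxidase, had 1.63 ± 0.33. Nrg4, a growth factor of the neuregulin family, had 2.20 ± 0.44, and Dennd2d, which activates Rab GTPases, had 2.37 ± 0.43. Lower at 28 months in estimate was Socs2, a brake on growth hormone signalling (ENSMUSG00000020027, chromosome 10, 95385362 to 95417180), at 11.1 ± 1.15 CPM (SD, n = 3) against 33.8 CPM, a log2 difference of -1.60 ± 0.25. Rcan1, an inhibitor of calcineurin, had -1.70 ± 0.28, and Gprc5c, an orphan receptor, had -1.85 ± 0.27. Igkv1-135, a segment of the immunoglobulin light chain, had -7.49 ± 1.01, with at most 0.0663 CPM in a 28-month library and 5.25 CPM at 18 months. Gapdh, a glycolytic enzyme whose processed pseudogenes resemble it in sequence, had -2.55 ± 0.32.

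Macrophages clear debris and present antigen, and their markers made up 1 of the 22 lists fixed for this comparison. All 15 measured macrophage and dendritic cell genes were higher at 28 months, with a median log2 difference of 0.99, and the limma camera test with a preset correlation gave an adjusted p of 6.4e-05. With an estimated correlation of 0.487 the camera adjusted p was 0.993, and the list was not called. In 11 of these genes the 18-month value lay below all 28-month values. Chance gives 25% for a single gene, but members of a list that move together are not independent, so this count was not tested. Cd68, a lysosomal protein of macrophages, had a log2 difference of 1.37 ± 0.37 (SE). C1qa and C1qc, chains of complement C1q, had 1.37 ± 0.46 and 1.30 ± 0.46, and Tyrobp, a signalling adaptor of myeloid cells, had 0.99 ± 0.35. Without 28-month replicate 2 the macrophage list had a median of 0.75 and missed the threshold, at a camera adjusted p of 0.0766.

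Schwann cells wrap motor and sensory axons in myelin. All 12 Schwann cell and nerve genes were lower at 28 months, with a median log2 difference of -1.26 and a camera adjusted p of 1.39e-05 under the preset correlation. With an estimated correlation of 0.619 the camera adjusted p was 0.993, and the list was not called. In 11 of the genes the 18-month value lay above all 28-month values. The 25% that chance gives for a single gene is again no measure for members that move together. Gjc3, a gap junction protein of myelinating glia, had a log2 difference of -1.91 ± 0.56 (SE), and Drp2, which anchors the outer Schwann cell membrane, had -1.56 ± 0.57. Under the preset correlation the Schwann cell call held when each 28-month library was left out, with an adjusted p of 0.000195 without replicate 2. The fry test called 0 lists, with an adjusted p of 0.985 for each. In every list, 0 members passed the edgeR test over all genes and 0 when adjusted over the list alone, beside the 753 genes at an unadjusted p under 0.05.

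**Figure D1:**
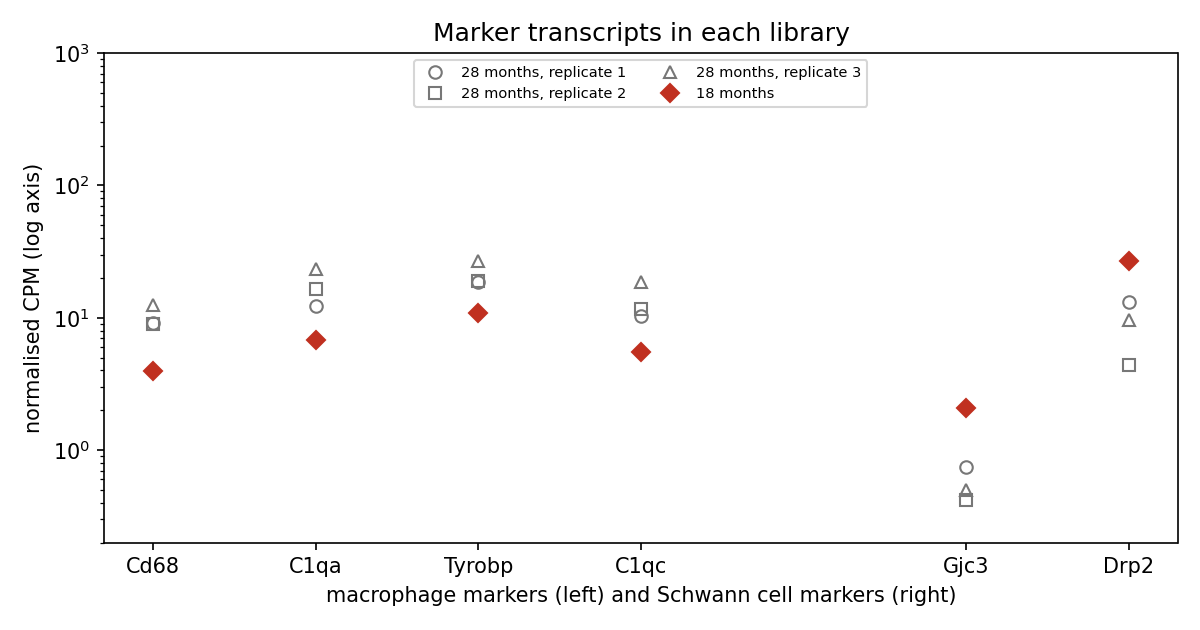
Normalised CPM on a log axis of macrophage markers (Cd68, C1qa, Tyrobp and C1qc) and Schwann cell markers (Gjc3 and Drp2), 1 point per library (grey open symbols for 28 months, red for 18 months). The 18-month library lay below all 28-month libraries for the macrophage markers and above them for the Schwann cell markers shown.

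The other 20 lists were not called on all 4 libraries. The markers of red blood cells, which carry haemoglobin, had a median log2 difference of 2.97 and an adjusted p of 0.355, and their CPM summed to 381, 146 and 3839 in 28-month replicates 1, 2 and 3 against 186 at 18 months. Median log2 differences were 0.78 for tendon, 0.79 for senescence and inflammation, 0.54 for adipocytes, 0.39 for interferon response and 0.30 for fast fibres. They were 0.23 for endothelium, 0.13 for smooth muscle and pericytes, 0.09 for oxidative phosphorylation, -0.00 for fibro-adipogenic progenitors and -0.01 for keratinocytes. They were -0.04 for the circadian clock, -0.05 for splicing factors, -0.10 for immediate early and heat shock genes, -0.26 for slow fibres and -0.43 for lymphocytes. In 4 lists the median was positive while camera leaned down, namely collagen and matrix (0.25), denervation (0.14), satellite cells (0.66) and muscle genes with known alternative exons (0.11). Without 28-month replicate 2 and under the preset correlation, 6 lists were called: Schwann cell (-0.97), collagen and matrix (-0.54), immediate early (-0.84) and fibro-adipogenic progenitor genes (-0.55) lower at 28 months, and fast fibre (0.52) and oxidative phosphorylation genes (0.25) higher. On all 4 libraries 0 lists were called by camera with an estimated correlation, which was not run without replicate 2. Leaving out replicate 1 gave 3 lists and leaving out replicate 3 gave 4, under the preset correlation.

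Of the genes fixed for their place in aging or muscle, none passed the edgeR test. Cdkn2a, which encodes the cell cycle inhibitor p16, had 5, 2 and 15 counts at 28 months and 0 at 18 months, too few to test. Cdkn1a, which encodes another such inhibitor, had a log2 difference of -0.03 ± 0.40 (SE) and the lamin gene Lmna had 0.29 ± 0.49. The myosin heavy chains of fast fibres Myh1, Myh2 and Myh4 had 0.34 ± 0.82, 0.42 ± 0.49 and -0.06 ± 0.69, and Myh7 of slow fibres had -0.26 ± 0.62. Collagens Col1a1, Col3a1 and Col6a3 had 0.24 ± 1.61, 0.29 ± 1.54 and -0.00 ± 1.34. Col3a1 stood at 42.1, 595 and 64.2 CPM in 28-month replicates 1, 2 and 3 and at 191 CPM at 18 months, and without replicate 2 its log2 difference was -1.82. The splicing factors Hnrnpa1, Srsf1, Srsf7 and Mbnl1 had -0.65 ± 0.27, -0.44 ± 0.38, 0.37 ± 0.34 and -0.61 ± 0.30. Of the sarcomere genes, the giant proteins Ttn and Neb had -1.07 ± 0.50 and 0.13 ± 0.62, the troponin Tnnt3 had 0.79 ± 0.65 and the Z-disc protein gene Ldb3 had 0.22 ± 0.56.

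Exon usage differed between the 18-month library and the 28-month libraries in 389 genes. The bins used less at 28 months were, where they could be placed, mostly pieces on the intron side of splice sites, and those used more were often the first bin of the gene. Genes of oxidative phosphorylation were over-represented (12 of 26 called), and splicing factor and collagen genes were not. The comparison did not match genes for abundance, and rare bins are easier to call in abundant genes. At 18 months oxidative phosphorylation genes summed to 17466 CPM and splicing factors to 4139 CPM. Muscle genes with known alternative exons summed to 106170 CPM, yet 5 of 35 were called, so the share called did not follow the sums throughout. Whether abundance gave this order of lists was not tested. In placed genes without intron-side, first and last bins, only 1 of the 12 oxidative phosphorylation genes still tested was called, which missed the threshold (odds ratio 13.6, adjusted exact p 0.315). This comparison addressed the stated purpose of the sequencing, alternative splicing between these ages.

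The edgeR test of bin use called 389 of 11000 genes (3.54%) and 525 of 143485 bins, of which 299 had higher and 226 lower use at 28 months. The count moved with single libraries: it was 226 genes without 28-month replicate 1, 3299 without replicate 2 and 164 without replicate 3. In genes whose bins could be placed on the reference, 147 of 311 called bins (47.3%) touched an exon from its intron side, against 6.28% of tested bins (odds ratio 13.8, two-sided Fisher's exact p 1.01e-90). Of these 147, 139 had lower use at 28 months. The first tested bin at the 5′ end of a gene made up 171 of the called bins (32.6%, against 7.66% of tested bins), and all 171 had higher use at 28 months. Genes with a processed pseudogene made up 28.8% of called genes against 15.7% of tested genes (odds ratio 2.26, two-sided Fisher's exact p 3.16e-11). With intron-side, first and last bins left out, 34 of 4994 placed genes were called.

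Each of the 12 genes with the smallest p is described by its most altered bin, as a share of the gene's tested counts. In 11 of them the bin was nearly unused at 28 months. Hspa9, a mitochondrial chaperone (ENSMUSG00000024359, bin 6), used the bin for 0.00593 ± 0.00379% (SD, n = 3) of counts at 28 months and 0.893% at 18 months (exact 95% interval 0.809 to 0.983). Cox6c, a subunit of cytochrome oxidase (ENSMUSG00000014313, bin 10), had 0.0581 ± 0.0292% against 7.04% (exact interval 6.73 to 7.36). Tnni2, the inhibitory troponin of fast fibres (ENSMUSG00000031097, bin 2), had 0.0374 ± 0.00635% against 6.70% (exact interval 6.64 to 6.76). Acadm, an enzyme of fatty acid oxidation (ENSMUSG00000062908, bin 12), had 0 counts in all 28-month libraries and 0.323% at 18 months, at least 102-fold lower at 28 months against the limit of 3 counts over the group. Capzb, which caps actin filaments, used 18 bases on the intron side of an exon (GRCm38 chromosome 4, 139288974 to 139288991) for 0.00370 ± 0.00447% against 0.694% (exact interval 0.599 to 0.800). The other bins lay in the glycolytic enzyme gene Ldha, the chaperone gene Hsp90ab1, the complex I gene Ndufa10, the signalling adaptor gene Ywhae, the mitochondrial ribosome gene Mrpl30 and the ATP synthase gene Atp5e. Their 18-month shares ran from 0.225% in Ywhae to 2.35% in Mrpl30. Pdlim5, a Z-disc scaffold with alternative exons (ENSMUSG00000028273, bin 12), went the other way, at 1.61 ± 0.167% at 28 months and 0 counts at 18 months, at least 155-fold higher at 28 months against the limit of 3 counts (0.0104%).

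**Figure D2:**
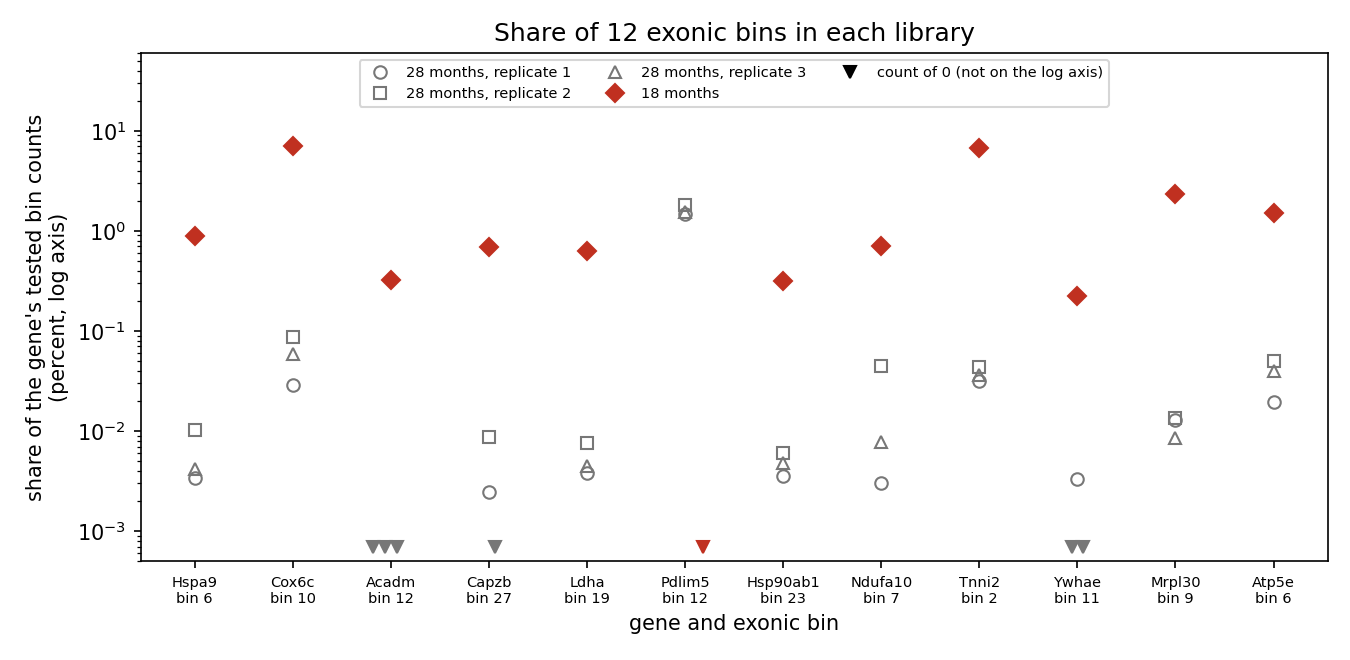
Share of the gene's tested counts (percent, log axis) taken by 1 bin of each of the 12 genes with the smallest p, 1 point per library, with counts of 0 drawn as filled triangles at the foot. The 18-month library lay above all 28-month libraries in 11 genes, and Pdlim5 had 0 counts at 18 months.

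Among the fixed genes, 3 were called by the Simes test per gene. Myh2 used a piece of its 5′ untranslated region (bin 2, chromosome 11, 67171066 to 67171088) for 0.409 ± 0.187% (SD, n = 3) of counts at 28 months, and had 0 counts there at 18 months. Mbnl1, a regulator of muscle splicing, used its first bin for 0.425 ± 0.0515% against 0.0240%, higher at 28 months. The Myh2 and Mbnl1 bins lie toward the 5′ end of their genes, and all 171 called first bins had higher use at 28 months. Neb, the giant protein that sets thin filament length, used bin 35 for 0.00958 ± 0.00774% against 0.0653%, lower at 28 months, and this bin missed the threshold without 28-month replicate 3 (edgeR adjusted p 0.0945). Ldb3 missed the threshold per gene at an edgeR Simes adjusted p of 0.0613, although its bin 11 passed in the test of single bins. That bin had 349, 111 and 6 counts in 28-month replicates 1, 2 and 3 and 1 at 18 months. Ttn, Tnnt3 and the other fixed genes were not called.

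Oxidative phosphorylation genes, which encode the respiratory chain, had 12 of 26 members called (46.2%) against 377 of 10974 other genes (3.44%), an odds ratio of 24.1 with an adjusted two-sided Fisher's exact p of 7.98e-11, and 14 were called when adjusted over the list alone. Muscle genes with known alternative exons had 5 of 35 called (14.3%), an odds ratio of 4.59 with an adjusted exact p of 0.0146, and 7 when adjusted over the list alone. The latter list missed the threshold without 28-month replicate 1, where its odds ratio was 4.51. It also missed it with the gene F-test, where 11 of 35 were called (31.4%, against 30.7% of other genes), an odds ratio of 1.04 with an adjusted exact p of 1. With the F-test the odds ratio of oxidative phosphorylation genes was 2.64, at an adjusted exact p of 0.0342. Splicing factors had 2 of 45 called (adjusted exact p 0.898), namely Mbnl1 and Tardbp, an RNA-binding protein named after its values were seen. Collagen and matrix genes had 0 of 24 called by edgeR and 0 when adjusted over the list alone. Without 28-month replicate 2 their odds ratio was 1.17, so they were called about as often as other genes. By the F-test on all 4 libraries, collagen and matrix genes had 0 of 24 called against 30.7% of other genes, fewer at an adjusted exact p of 0.000836. This count cannot tell steadier exon usage from lost power. Matrix genes stood higher in 28-month replicate 2 by a median log2 of 1.98 against the mean of replicates 1 and 3. On simulated data with a shared gene effect, the Simes test recovered 0% of changes. With only placed genes kept and intron-side, first and last bins left out as well, 0 lists were called, with 4994 genes tested and 34 called. There 1 of 12 oxidative phosphorylation genes was called, an odds ratio of 13.6 with an adjusted exact p of 0.315.

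The 18-month library stood further in exon usage from each 28-month library than these stood from each other. This comparison measured the distance without a test, since 4 libraries are too few for a permutation p under the threshold. The mean absolute difference in bin share was 0.990 ± 0.0593 percentage points (SD over 3 pairs) within 28 months and 2.07 ± 0.0455 across ages (3 pairs), a ratio of 2.09, over 10075 genes in libraries thinned to the same total count, which leaves the depth of single genes unequal. Pairs share libraries and are not independent. Without first and last bins the ratio was 1.70.

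**Figure D3:**
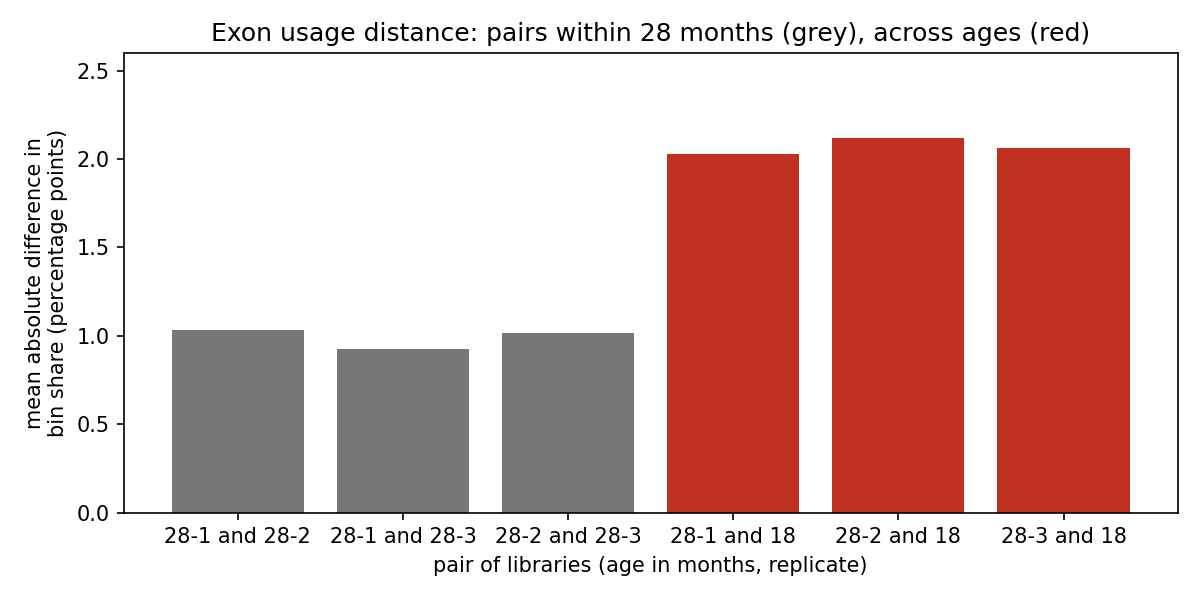
Mean absolute difference in bin share (percentage points) for each of the 6 pairs of libraries, grey within 28 months and red across ages. The pairs across ages averaged 2.07 and those within 28 months 0.990.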

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

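The tests chosen only after the result was seen were the GC content tests on replicate 2, the tests of junction reads, of the bin further into the intron, of 3′ coverage, of other splits of the libraries, of more mitochondria, and of joined bins without mitochondrial ones. Bins that join several genes, which the gene test used and the exon usage test did not, took 8.74% of counts at 18 months (6.51, 6.57 and 6.31% in 28-month replicates 1, 2 and 3). Mitochondrial bins made up this excess: without them the share was 4.34% at 18 months and 4.52 to 4.998% at 28 months, so it is part of the mitochondrial pattern. Fragments outside annotated exons, which no comparison used, were 2.90% at 18 months (1.75, 2.74 and 1.67% at 28 months), so 28-month replicate 2 was about as high and the value did not set the 18-month library apart.

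28-month replicate 2 stood apart, with matrix genes higher by a median log2 of 1.98 and fast fibre genes by -1.03 against the mean of replicates 1 and 3. Immediate early and heat shock genes (1.64, 16 of 17 members higher) and satellite cell genes (1.58, 8 of 9 members higher) were also higher in replicate 2. Removing GC content and length trends argued against these as the whole cause, since its distance remained 2.38 times that between replicates 1 and 3 (2.64 before). More connective tissue, fat and vessel cells in the piece of muscle cannot be told apart from other causes: the medians were 1.16 for fibro-adipogenic progenitors, 0.66 for adipocytes and 0.80 for endothelium, and the lowest, 0.30 for smooth muscle, fell between the bounds set for it. Schwann cell markers were lower in replicate 2 (-1.15), so a loss of fibre share alone would not give this profile. Red blood cell markers were lower too (-2.83), but replicate 3 carried this value: their CPM summed to 381, 146 and 3839 in replicates 1, 2 and 3. A difference between animals of this age remains open and was not tested.

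Exon usage set the 18-month library apart, and coverage nearer the 3′ end is a candidate cause for the first bins: the 3′ part of the bins held a median 71.8% of counts at 18 months, 7.73 points above the highest 28-month library (62.1 to 64.1%, 8819 genes), although over internal exons of 61 to 150 bases the gap was far smaller (54.5% against 51.8 to 53.6%, 1804 genes). For intron-side bins, misplaced junction reads may contribute, but the tests were mixed: a first test, over all such bins of constitutively spliced genes, gave 1.15 times the highest 28-month library, between its bounds of 1 and 1.5, and a second, run after that on rarely used bins alone, gave 2.58 times. Retained introns were tested in 2 ways that differed: long bins rose more than short ones by a log2 of 0.31, as the length test, set before, had required of retention, whereas the next bin further into the intron rose less than the touching bin by -1.45 (95% bootstrap interval -2.02 to -0.94, 73 pairs), so retention is argued against only where a further bin is annotated and stays open elsewhere. Only 4 splits of the libraries exist, too few for a share under 0.05, and the real split gave 389 genes and was the 1 split to reach that number, with 68 for the highest other; for gene expression all 4 splits reached the real count of 0, with 17 for the highest other. Every split reaches a count of 0, so the splits could decide nothing for gene expression. Age, and a library batch that the labels do not give, remain open for the whole exon usage pattern.

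Mitochondrially encoded transcripts took 14.0% of counts at 18 months against 5.01 to 5.98% at 28 months, and the 6 protein genes with their own unit had a median log2 difference of -1.30. Among them mt-Co2 did not follow, at -0.16, with 250, 14.3 and 259 CPM in 28-month replicates 1, 2 and 3 against 195 CPM at 18 months. Over the 4 libraries mt-Nd3 stood near the floor, at 0.419 to 1.01 CPM, and mt-Co1 at 15657 to 58295 CPM. Why these units were counted at such different levels was not tested. No mitochondrial gene passed the edgeR test on all 4 libraries, and 4 of the 6 did without 28-month replicate 2. Removing GC content and length trends left the median at -1.19, which argues against these trends as the whole cause. More mitochondria in the 18-month muscle cannot be told apart from other causes: nuclear oxidative phosphorylation genes had a median of 0.087 (quartiles -0.065 to 0.42), above the bound of -0.3 written after that value was known, yet members went both ways and nuclear transcripts need not follow the number of mitochondria. Age and RNA handling remain open and were not tested.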

How the results depend on the processing

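Chosen after seeing the data were the alternatives that removed GC and length trends, used quality weights, or restricted exon usage and its distance to placed genes or to genes with no processed pseudogene. No paired analysis was possible because the 18-month group has 1 library. Unless stated, the cause of a shift was not tested.

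Genes called for expression, 0 by edgeR on all 4 libraries (753 at an unadjusted p under 0.05), ranged from 1 to 1806 when 1 library of 28 months was left out (2 without replicate 1, 1806 without replicate 2 and 1 without replicate 3). The DESeq2 Wald test called 34, removing GC and length trends 7, the same without replicate 2 2157, and limma voom with quality weights 1. Of the 1806, 1325 were also called in the same direction without replicate 2 and with trends removed. In replicate 2 alone, 1228 of them (68.0%) had the same direction. Both directions were taken against the same lone library of the younger age, so they can match without any effect of age. The share expected from this alone was not worked out, so the 1228 cannot show whether replicate 2 repeats the calls. DESeq2 size factors, count filters and the library size without abundant genes left 0.

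Log2 differences of fixed genes, none past the threshold on all 4 libraries, reversed in 24 cases. With 1 library left out, values ranged from -0.25 to 0.20 for Cdkn1a, -0.14 to 0.75 for Myh1, -0.32 to 0.18 for Myh4, -0.84 to 0.036 for Myh7, -1.997 to 0.76 for Col1a1, -1.82 to 0.79 for Col3a1, -1.78 to 0.44 for Col6a3 and -0.11 to 0.41 for Neb. With trends removed, Myh4 was 0.023, Col1a1 -0.19 and Col3a1 -0.063. With trends removed and without replicate 2, Cdkn1a was 0.12, Myh4 0.39, Myh7 0.097, Col1a1 -2.02 and Col3a1 -1.62. With quality weights, Cdkn1a was 0.19, Myh4 0.19, Myh7 0.074, Col1a1 -1.74 and Col3a1 -1.62. Col6a3, near 0, was 0.013 with no filter and 0.00098 at a mean count of at least 50. Other values of named genes kept direction and side in 244 cases and gained significance in 51.

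Exon usage, 389 genes and 525 bins, ranged from 164 to 3299 genes and from 224 to 9835 bins with 1 library left out (226 without replicate 1, 3299 without replicate 2 and 164 without replicate 3). It was 234 genes and 298 bins at a mean bin count of at least 30, and 206 and 305 without first and last bins, where fewer bins were tested. The gene F-test called 3375 genes, limma voom 1765 genes and 3435 bins, and DESeq2 5925 and 24989. Placed genes gave 217 and 300, placed genes without intron-side and end bins 34 and 41, the same without replicate 2 655 and 1707, and genes with no processed pseudogene 259 and 330. No named bin reversed in the alternatives run, but calls were lost in 8 cases: 5 for Ldb3 bin 11, 2 for Neb bin 35 (without replicate 3 and by DESeq2) and 1 for Myh2 bin 2 (by limma voom). Bins not called on all 4 libraries gained a call in 13 cases.

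Exon usage lists called, 2 on all 4 libraries, ranged from 1 to 2 with 1 library left out, and were 0 in placed genes without intron-side and end bins, where the odds ratios of splicing factors and of muscle alternative exons were 0 and 0. Oxidative phosphorylation was no longer called there: 1 of 12 genes was called, an odds ratio of 13.6 (24.1 before) with an adjusted exact p of 0.315, with fewer genes tested. With the gene F-test 2 lists were called, but not the same 2: muscle alternative exons were lost (odds ratio 1.04, adjusted exact p 1), oxidative phosphorylation had an odds ratio of 2.64, and collagen had fewer calls than other genes (0 of 24, adjusted exact p 0.000836). The collagen odds ratio by the Simes test became 1.17 without replicate 2. Whether lost power gave the low F-test count was not tested.

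Expression lists called, 2 on all 4 libraries, ranged from 3 to 6 with 1 library left out and were 4 with trends removed, 0 with an estimated correlation and 0 with fry. Medians that reversed with 1 library left out ranged from -0.84 to 0.24 for immediate early genes, -0.55 to 0.27 for fibro-adipogenic progenitors, -0.068 to 0.25 for oxidative phosphorylation, -0.54 to 0.64 for matrix, -0.056 to 0.39 for endothelium, -0.18 to 0.18 for keratinocytes, -0.54 to 1.07 for satellite cells, -0.65 to 0.036 for slow fibres, -0.11 to 0.33 for denervation, -0.025 to 0.27 for muscle alternative exons and -0.032 to 0.0069 for splicing factors. With trends removed, matrix was -0.0016 and splicing factors 0.017.

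The ratio of exon usage distances, 2.09, was 2.57 at a mean count of at least 1000, 4.91 as median Jensen-Shannon divergence, 1.70 without first and last bins and 1.75 in placed genes without intron-side and end bins. It stayed above 1 in each. Among simulated changed genes, all with a mean count of at least 100, the spread between libraries limited the gene test. It recovered 44% of changes of log2 2 with the spread of all 4 libraries and 86% with the spread left without replicate 2. Both simulations drew all 4 libraries, so the power of the fit without replicate 2 was not measured. Genes of lower count, where counting error is larger, were not simulated as changed.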

Other observations

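All observations in this part were chosen after the values were seen. Counts on processed pseudogenes, copies of spliced transcripts in the genome, were lower at 28 months in 736 of 883 cases (83.4%), with a median log2 difference of -0.45. Whether these reads came from the copies or from their parent genes was not tested. Coding genes with no such copy were lower in 41.3% of 11081 cases, with a median of 0.11.

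Internal exons of 61 to 100 bases had a smaller share of their gene's counts at 18 months, by a median log2 of -0.51, and exons of over 300 bases by -0.10. Rarely used intron-side bins of over 1000 bases (71 bins) held 0.824% of the counts of the adjoining exon at 18 months, within the 0.356 to 1.18% of the 28-month libraries, while those of 10 bases or less (74 bins) held 2.18% against 0.326 to 0.818%.

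Without 28-month replicate 2, some of the genes with the largest differences by edgeR are given here, picked from a longer list and not tested as a group. Acly, which makes acetyl-CoA for fat synthesis, had a log2 difference of 3.95, Angptl8, a hormone of fed animals, 3.84, Gys2, a glycogen synthase, 3.46, and Ppp1r3b, which activates glycogen synthase, 2.80. Lower at 28 months were Nr4a2, an early response gene, at -2.80, Rpl10a, a ribosomal protein gene, at -3.33, and Amd1, an enzyme of polyamine synthesis, at -2.88. The similarly named Amd2 (-2.70), Amd-ps3 (-2.54) and Amd-ps4 (-2.97) moved with Amd1, and reads shared among such copies were not told apart. In replicate 2 itself Acly stood at 147 CPM, against 1045 CPM in replicate 3 and 90.1 CPM at 18 months. Amd1 stood at 263 CPM in replicate 2 against 489 CPM at 18 months, Nr4a2 at 7.04 against 8.92 CPM, and Rpl10a at 5.03 against 20.9 CPM.

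Tnnt3, a troponin with many alternative exons, had 101673 counts in bin 11 of 28-month replicate 2, against 49 and 54 in replicates 1 and 3 and 25 at 18 months. The use of this bin set replicate 2 apart from the other libraries of either age.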
